A study of Danio rerio with 23 samples.

How the data were processed

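Gene expression was measured in the gut of adult zebrafish, 8 months old per the labels, on 23 Agilent one-colour arrays. The labels give 6 control females, 7 females exposed to DEHP (bis(2-ethylhexyl) phthalate, a plasticiser), 5 control males and 5 exposed males, with 1 array per numbered fish. The labels give the same dose level, 3 ppm, for all exposed fish. Whether the dose was given in water or in feed, and for how long, is not in the labels. No fish number appears in more than 1 group, so the arrays were treated as unpaired. The labels do not say whether each RNA came from a single animal beyond its fish number, so the p-values measure the spread between samples.

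Per the labels, total RNA was extracted with Trizol and labelled with Cy3 by the Agilent one-colour protocol. Per the file headers, each array file holds Feature Extraction intensity values (version 10.1.1.1), with the processed green signal as a background-subtracted and spatially detrended intensity in which surrogate values replace very low signals. The submitters' processing notes name version 10.7 instead. The deposited value table is in log2 units. Its 23 columns share 1 set of sorted values with a median of 4.41, equal to quantile-normalised log2 processed signal with a floor of 1.8. Each column correlated with the log2 signal of its own array at r between 0.960 and 0.999, and 0 columns were left unmapped. How the authors made the table is not stated, so the array files were used and the deposited table served as an alternative.

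The arrays hold 43803 non-control features for 43603 probes. Names were updated with the gene records supplied for the species. An accession named 27276 probes, 7975 carried a current symbol in the file, 370 were named through a synonym and 7982 kept the name in the file. A gene symbol was then held by 32297 probes, for 16706 genes, and 11306 probes had a placeholder name only. Probe positions are on build danRer7, per the file headers; no sequence of that build was used here, so exon or intron positions of the probes are not known. Positions are written as chromosome, start and end.

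Processed signals were put on the log2 scale and the 75th percentile of the non-control features of each array was subtracted, so that a level of 0 is the 75th percentile of that array. Non-uniform and population outlier spots were set to missing, which removed 251 of 694140 values among tested probes. Spots of the same probe were averaged. A probe was tested when it was well above background, by the flag in the file, on at least 5 of the 23 arrays. This left 30180 probes for 17949 genes, 13048 of them with a symbol, and 12966 probes were well above background on all 23 arrays. Gene lists and gene counts used the brightest tested probe of each gene. The choices in this paragraph and the next, with the gene lists, were made before the data were examined.

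A mean per group was fitted to all 23 arrays with limma 3.58.1 (lmFit and eBayes, two-sided, prior degrees of freedom 3.61) in R 4.3.3. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, with the R package data.table (version 1.17.8), prepared and drew the data. The 6 contrasts were DEHP minus control in females, in males and over both sexes (the mean of the sex-specific effects), the female minus the male DEHP effect, and females minus males among controls and among exposed fish. Benjamini-Hochberg adjustment ran over all tested probes of a contrast, with a threshold of 0.05. For each contrast the genes named were, among those past the threshold, the 6 largest rises and the 6 largest falls. Where fewer than 10 passed, genes with the smallest p were added until 10 were named, as values that did not pass. For each gene list past its threshold, or with at least 2 members past the threshold, up to 4 members with the smallest p were named. At most 30 genes were named per contrast by these parts. Genes with placeholder names stayed in the counts. The targets pparaa, cyp1a, cyp3a65, nr1i2 and vtg1 were given in the exposure contrasts whatever their values. Where a gene was not well above background on any array of the lower group, the fold is written as a lower bound. The lower group was then set, array by array, to the lowest signal well above background on that array, or to the signal of the probe where that was higher.

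The 39 gene lists were fixed by name from general knowledge, the ribosomal proteins by their symbols. They were tested with camera at its preset inter-gene correlation of 0.01, with adjustment over the 39 lists. They cover metabolism, stress, immune and epithelial programmes of the gut, and other tissues that a dissected gut can carry, such as pancreas, liver, ovary, testis, muscle and blood. Each list had at least 5 measured members, from 10 to 87. Some lists share genes: enteroendocrine cells and endocrine pancreas share 10, complement and liver share 6, and liver and iron response share 3. Alternatives were an estimated correlation, fry, and, added after the data were seen, an exact permutation test of the list mean per array between the 2 groups of a contrast (two-sided).

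The arrays lie on 7 slides of 1 to 4 arrays, and were scanned in 2 scans of 12 and 11 arrays with all 4 groups in each. The consensus correlation of arrays on a slide was 0.0734. Within slides, DEHP effects could be taken on 3 slides for females and on 4 for males. Other settings fixed beforehand were normexp background correction with an offset of 50, quantile normalisation, median scaling, no expression filter, a filter on all arrays, the deposited table, slide as fixed or random block, scan as block, a fit of only the 2 groups compared, array weights, a trended and robust prior, an exocrine pancreas covariate, an adjusted p of 0.1, an unadjusted p of 0.05 with 1.5-fold change, gene means, and leaving out each array. Added after the data were seen were fits without control females 71 and 76, and with array brightness, the fish number, or the liver, ovary and exocrine pancreas levels as covariates. Each count was also compared with 100 regroupings of the samples.

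The method was tested on simulated data built from these arrays. Of 100 probes given a change of 2 on the log2 scale, 68% were recovered in females, 54% in males and 75% over both sexes, with 2 false of 82 calls, 5 of 65 and 11 of 117. For a change of 1, recovery was 12%, 6% and 31%. A shift of 0.5 given to the circadian clock list was called and 0 of the 38 other lists were. The simulated genes varied independently of each other, so this could not show false list calls from genes that move together. The number of arrays limits the precision of all values.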

Results

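Transcript levels in the gut of adult zebrafish were measured on 23 one-colour arrays, from fish exposed to the plasticiser DEHP at 3 ppm and from controls at 0 ppm. The groups held 6 control females, 7 exposed females, 5 control males and 5 exposed males. The median over arrays of the 75th percentile signal, in intensity units, was 182 in control females, 155 in exposed females, 81.9 in control males and 129 in exposed males. Between 39.7% and 86.0% of probes were well above background on the control female arrays, 51.4% to 67.8% on exposed female arrays, 41.4% to 65.6% on control male arrays and 47.6% to 60.9% on exposed male arrays. Arrays of the same group correlated at a median r of 0.918 across genes, each by its brightest tested probe, against 0.902 between groups. Genes are not independent replicates. Levels below are log2 signal relative to the 75th percentile of the array, errors of fold changes are standard errors (SE), and errors of group levels are standard deviations (SD). Positions are on build danRer7. In the labels the fish numbers of all controls are below those of all exposed fish.

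The first question was how DEHP changed the gut transcriptome of females, the exposure contrast named by the study design. Genes of the circadian clock led the differences between exposed and control females. The transcript of nfil3-5, a transcriptional repressor of the NFIL3 family, was 7.70-fold higher in exposed females (log2 fold change 2.94, SE 0.43, adjusted p 0.00885). Its level was -1.47 ± 0.96 (SD, n = 6) in controls and 1.47 ± 0.90 (SD, n = 7) in exposed females, and 7 of 7 exposed arrays lay above the control mean (probe on chromosome 6, 9616264 to 9616323). The photolyase-like gene cry5 fell 4.92-fold (log2 -2.30, SE 0.38, adjusted p 0.0153; chromosome 10, 40632503 to 40632566). The PAR bZIP transcription factor gene dbpa fell 4.64-fold (log2 -2.22, SE 0.37, adjusted p 0.0153; chromosome 19, 10800874 to 10800933). Its relative tefa fell 3.42-fold (SE 0.32, adjusted p 0.0289), and the cryptochrome gene cry2 fell 3.05-fold (SE 0.27, adjusted p 0.0153; chromosome 25, 4289172 to 4289231). For cry5, dbpa, tefa and cry2 all 7 exposed arrays lay below every control array. Of the 30 measured members of the circadian clock list, 1 rose, 4 fell and 25 did not pass; 2 rose and 9 fell adjusted over the list alone. The list shifted down (mean log2 fold change -0.47, 7 of 7 exposed arrays below the control mean, adjusted p 0.00123), with adjusted p = 0.241 with an estimated correlation and an exact permutation p of 0.000583 for the list mean per array (adjusted 0.0227).

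Outside the clock list, angptl1a, an angiopoietin-like gene, was at least 1.57-fold lower in exposed females (adjusted p 0.0239, 7 of 7 arrays below every control array), and ankrd9, an ankyrin repeat gene, fell 3.71-fold (SE 0.35, adjusted p 0.0355, 7 of 7 below the control mean). The genes next by p did not pass in females: cry3b (log2 fold change 1.55, adjusted p 0.0646), nr1d1 (-2.59, adjusted p 0.0646) and ciarta (-1.88, adjusted p 0.0726). In all, 17 of 30180 probes passed, 3 higher and 14 lower, from 2 higher and 9 lower genes, and 3045 had an unadjusted p under 0.05 where 1509 were expected by chance. The self-test recovered 68% of probes with a change of 2 on the log2 scale and 12% with a change of 1. With slide as a fixed block 0 probes passed limma's test, with 2170 at an unadjusted p under 0.05 (nfil3-5 3.06, adjusted p 0.219; cry2 -1.60, adjusted p 0.41). Within slides nfil3-5 was higher on each of 3 slides (2.72 to 4.36) and cry5, dbpa and cry2 were lower on each (-2.66 to -1.54, -4.24 to -1.44 and -2.07 to -0.95). By limma 0 probes passed without control females 71 and 76 (1167 unadjusted) or with the fish number as a covariate (543 unadjusted; nfil3-5 1.92, SE 0.72), and the clock list was not called with that covariate (adjusted p 0.312).

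Markers of pancreatic endocrine cells shifted down in exposed females. The 18 members of the endocrine pancreas list had a mean log2 fold change of -0.79, with 0 past the threshold over all genes, 5 lower adjusted over the list alone, and 7 of 7 exposed arrays below the control mean (adjusted p 6.89e-05; adjusted p = 0.241 with an estimated correlation; exact permutation p 0.00932 for the list mean). Examples that did not pass were the prohormone convertase genes pcsk1 (log2 fold change -1.83, adjusted p 0.288) and pcsk2 (-1.69, adjusted p 0.295; 0.10 with the fish number as covariate), the islet transcription factor gene pax6b (-0.83, adjusted p 0.301) and rasd4 (-1.29, adjusted p 0.35). Within the 3 slides the list mean was lower on each (-1.45 to -0.41). The 22 genes of the erythrocyte list also shifted down (mean -0.57, 7 of 7 arrays, adjusted p 0.00519; adjusted p = 0.428 with an estimated correlation). Values were -1.45 for the anion exchanger gene slc4a1a, -0.98 and -1.58 for the globin genes hbba1 and hbba2, and -1.23 for rhag, none past the threshold. On 2 of 3 slides the erythrocyte mean was lower. The cholesterol synthesis list shifted down as well (mean -0.49, 26 genes, adjusted p 0.0359; adjusted p = 0.803 with an estimated correlation), and its call was lost with slide as a block (adjusted p 0.106) but not with the fish number as covariate (mean -1.40, adjusted p 6.02e-12).

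Transcripts of ovary and oocytes shifted up in exposed females. All 45 members of the ovary and oocytes list failed the threshold one by one, in counts over all genes and adjusted over the list alone, and their mean log2 fold change was 1.48 (adjusted p 1.09e-09; adjusted p = 0.803 with an estimated correlation; exact permutation p 0.189 for the list mean). Values were 3.35 for the egg coat gene zp3.2 (adjusted p 0.418), 2.49 for the maternal transcription factor gene pou5f3, 3.06 for ca15b and 1.04 for the oocyte kinase gene wee2. The list mean ranged from -3.78 to 1.95 over control females and from -3.01 to 1.71 over exposed females, so 0 exposed arrays lay beyond every control array, and the female difference was positive on 2 of 3 slides (-3.38 to 4.69). The cell proliferation list, 52 genes, moved with it (mean 0.36, 5 of 7 exposed arrays above the control mean, 2 of 3 slides, adjusted p 0.00101; adjusted p = 0.803 with an estimated correlation). Its members included the mitotic genes aurkb at 1.11, birc5a at 1.11 and plk1 at 0.94, and the chromatin gene hmgb2a at -1.53, none past the threshold. The lysosome-rich enterocyte list, whose cells take up luminal protein, also shifted up (mean 0.30, 40 genes, 6 of 7 arrays, 2 of 3 slides, adjusted p 7.61e-05, and adjusted p = 0.803 with an estimated correlation). The lysosomal protease gene ctsd stood at 5.42 in control and 6.32 in exposed females, with 7 of 7 exposed arrays above every control array (log2 0.90, SE 0.21, adjusted p 0.139, the 1 member past the threshold adjusted over the list alone). The lysosomal genes ctsla (1.03), acp5a (1.45) and npc2.2 (0.72) did not pass.

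The remaining 3 upward calls in females were small: exocrine pancreas (mean 0.20, 38 genes, adjusted p 0.00519, 6 of 7 arrays), tight junction and epithelial adhesion (0.14, 51 genes, adjusted p 0.0369) and ribosomal proteins (0.10, 87 genes, adjusted p 0.0149), each with 0 members past the threshold. With an estimated correlation adjusted p = 0.803, 0.464 and 0.85. With quantile normalization all 3 were lost (adjusted p 0.906, 0.116 and 0.124) and the ribosomal proteins turned down. The tight junction call was also lost with slide as a fixed block (adjusted p 0.0638) and with the fish number as covariate (0.540). Quantile normalization moved the median of all probes from -0.09 to 0.08 in females. The fixed targets did not pass: pparaa, the nuclear receptor that drives fatty acid oxidation genes (-0.03, SE 0.24, adjusted p 0.971), cyp1a, a target of the aryl hydrocarbon receptor (-0.76, adjusted p 0.552), and the intestinal cytochrome P450 gene cyp3a65 (0.40, adjusted p 0.722). Neither did the pregnane X receptor gene nr1i2 (-0.23, adjusted p 0.84; 0.53 with quantile normalization) and the yolk protein gene vtg1 (-0.27, adjusted p 0.96). The fatty acid oxidation and PPAR alpha targets list gave a mean of 0.09 (37 genes, adjusted p 0.0541).

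The second question was the same exposure in males. Again clock genes led. nfil3-5 rose 17.1-fold (log2 4.09, SE 0.49, adjusted p 0.000643), from -2.30 ± 0.73 to 1.79 ± 0.35 (SD, n = 5 each). The haem-binding nuclear receptor gene nr1d1, a repressor of the clock, fell 16.7-fold (log2 -4.06, SE 0.59, adjusted p 0.00581), from 2.02 ± 0.65 to -2.04 ± 1.15 (chromosome 3, 23787155 to 23787214). The clock repressor gene ciarta fell 7.10-fold (log2 -2.83, SE 0.44, adjusted p 0.0105; chromosome 19, 9550983 to 9551042). For each of these genes 5 of 5 exposed arrays lay beyond every control array. Of the 30 clock list members 1 rose, 2 fell and 27 did not pass, and 5 rose and 9 fell adjusted over the list alone. The list shifted down (mean -0.41, 5 of 5 exposed arrays below the control mean, adjusted p 5.49e-05; adjusted p = 0.138 with an estimated correlation). Named genes that did not pass were cry2 (-1.62, adjusted p 0.0564), tmem116 (1.63, adjusted p 0.107), kctd12.1 (lower, adjusted p 0.118), znf395b (-1.98), cry3b (1.69) and the heat shock factor gene hsf2 (-1.59), each of these with adjusted p 0.134, and dbpa (-1.98, adjusted p 0.136).

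In all, 8 probes passed in males, 2 higher and 6 lower, from 1 higher and 4 lower genes, and 1153 had an unadjusted p under 0.05, fewer than the 1509 expected by chance. The self-test recovered 54% of changes of 2 and 6% of changes of 1 on the log2 scale. The fit with slide as a fixed block passed 2 probes (nfil3-5 4.28, adjusted p 0.00552; nr1d1 -4.12, adjusted p 0.0794; ciarta -2.80, adjusted p 0.147). Within 4 slides nfil3-5 was higher on each (3.36 to 4.93), and nr1d1 (-5.63 to -2.44) and ciarta (-4.14 to -1.51) were lower on each. With normexp background correction, or with the fish number as a covariate, limma called 0 probes, with 605 and 1181 at an unadjusted p under 0.05 (nfil3-5 2.93, SE 0.82, adjusted p 0.961 with the number), and the clock list was not called with the number (adjusted p 0.413).

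Several lists of other digestive tissues shifted down in exposed males, without a member past the threshold. The digestive enzyme genes of the exocrine pancreas list had a mean log2 fold change of -0.59 (38 genes, 5 of 5 exposed arrays below the control mean and lower on 4 of 4 slides, adjusted p 1.46e-09; adjusted p = 0.272 with an estimated correlation). Single genes were c6ast4 at -1.28, the phospholipase gene pla2g1b at -1.19, the elastase gene cela1.1 at -0.72 and the chymotrypsinogen gene ctrb.3 at -0.63, of which pla2g1b turned to 0.05 with the fish number as covariate. The liver list followed (mean -1.05, 55 genes, 4 of 5 arrays, 3 of 4 slides, adjusted p 2.98e-08; adjusted p = 0.532 with an estimated correlation). Its members included agxta at -1.03, the growth factor gene igf1 at -2.14, cyp2ad2 at -1.53 and the kininogen gene kng1 at -1.55. The complement list (-0.64, adjusted p 0.0354) and the vitellogenin list (-1.06, adjusted p 0.0174) were also lower, with adjusted p = 0.865 and 0.605 with an estimated correlation. The vitellogenin shift rested on control males 77 and 92 (list means 2.63 and 2.27), as the other 3 controls lay at -1.87 to -1.19, below 4 of 5 exposed males (exact permutation p 0.373). With the fish number as covariate the liver call was lost (adjusted p 0.863, mean turning to 0.31), as were those of complement (0.172, turning to 0.85), vitellogenins (0.0661) and endocrine pancreas (0.0907). The vitellogenin call was lost with slide as a block as well (adjusted p 0.0584). The endocrine pancreas list shifted down as in females (mean -0.66, 18 genes, 5 of 5 arrays, 4 of 4 slides, adjusted p 5.49e-05; adjusted p = 0.15 with an estimated correlation). Its hormone genes stood at -1.79 for insulin (ins), -1.77 and -1.48 for the somatostatin genes sst1.1 and sst1.2, and -1.33 and -1.43 for the glucagon genes gcga and gcgb, none past the threshold. The enteroendocrine list, which shares 10 genes with it, had a mean of -0.34 (adjusted p 0.00293; adjusted p = 0.378 with an estimated correlation).

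Smaller downward shifts in males were called for xenobiotic metabolism and transport (mean -0.29, 52 genes, adjusted p 0.00761), extracellular matrix (-0.28, adjusted p 0.00907), lipid absorption and lipoprotein assembly (-0.25, adjusted p 0.0138) and fatty acid synthesis (-0.48, adjusted p 0.0147). Others were heat shock response (-0.28, adjusted p 0.0174), erythrocytes (-0.32, adjusted p 0.0251), nuclear receptors and steroid hormone handling (-0.21, adjusted p 0.0309) and unfolded protein response (-0.13, adjusted p 0.0341). Members of the xenobiotic list stood at -0.87 (ugt5a1), -1.10 (cyp1a), -0.73 (abcb4) and -1.43 (gsta.2), and those of the matrix list at -1.03 (ogna) and 0.54 (mmp14b), none past the threshold, ogna turning to 0.21 with normexp background correction, and ugt5a1 and gsta.2 to 0.04 and 0.22 with the fish number as covariate. Upward shifts were called for myeloid cells (0.29, 40 genes, adjusted p 0.0108), T and NK cells (0.31, 29 genes, adjusted p 0.0158), skeletal muscle (0.52, 34 genes, adjusted p 0.0286) and innate inflammation (0.24, 53 genes, adjusted p 0.0394). Of the 19 lists called in males, 0 were called by camera with an estimated correlation (smallest adjusted p 0.138), 0 by fry and 0 by the exact permutation test, with 6 at an unadjusted exact p under 0.05. With normexp background correction, which moved the median of all probes from 0.00 to 0.12 in males, myeloid cells (adjusted p 0.765), innate inflammation (0.163) and erythrocytes (0.217) were lost, and the unfolded protein response with median scaling over tested probes (0.0501). The innate inflammation call was lost with slide as a block (0.0584). The fish number as covariate ended the calls of xenobiotic metabolism (adjusted p 0.113), matrix (0.129), heat shock response (0.507, mean turning to 0.03), unfolded protein response (0.142), myeloid cells (0.184) and T and NK cells (0.172). The targets pparaa (0.18, SE 0.27), cyp3a65 (-0.27), nr1i2 (-0.40) and vtg1 (-1.57) each had an adjusted p of 1.

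Taking the mean of the female and male effects, the exposure question over both sexes, gave 95 probes past the threshold, 34 higher and 61 lower, from 24 higher and 34 lower genes. Here nfil3-5 rose 11.5-fold (log2 3.52, SE 0.32, adjusted p 6.06e-06, 12 of 12 exposed arrays above the control mean of their sex). The cryptochrome gene cry3b rose 3.07-fold (SE 0.24, adjusted p 0.000943), and tmem116, a membrane protein gene, 2.52-fold (SE 0.22, adjusted p 0.00365, 11 of 12 arrays). Further rises were those of gdf6a, a growth factor gene of the BMP family (3.02-fold, SE 0.35, adjusted p 0.049), aif1l, which encodes an actin-binding protein (2.61-fold, SE 0.27, adjusted p 0.0218), and ypel3 (2.33-fold, SE 0.24, adjusted p 0.0255), each in 12 of 12 arrays. Among the falls were nr1d1 (log2 -3.33, SE 0.39, adjusted p 0.000144), ciarta (5.11-fold lower, log2 -2.35, SE 0.29, adjusted p 0.000169) and dbpa (4.28-fold lower, SE 0.28, adjusted p 0.000337), each in 12 of 12 arrays. The period gene per1b fell 4.17-fold (log2 -2.06, SE 0.33, adjusted p 0.00287; chromosome 7, 52301381 to 52301440), cry5 4.12-fold (SE 0.29, adjusted p 0.000752) and cry2 3.06-fold (SE 0.20, adjusted p 0.00017), again in 12 of 12 arrays. The ubiquitin ligase gene mylipb fell 4.19-fold (SE 0.42, adjusted p 0.0302) in 11 of 12 arrays. Over the 23 fits that left out 1 array, gdf6a passed in only 4, mylipb in 13 and ypel3 in 15.

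**Figure D1:**
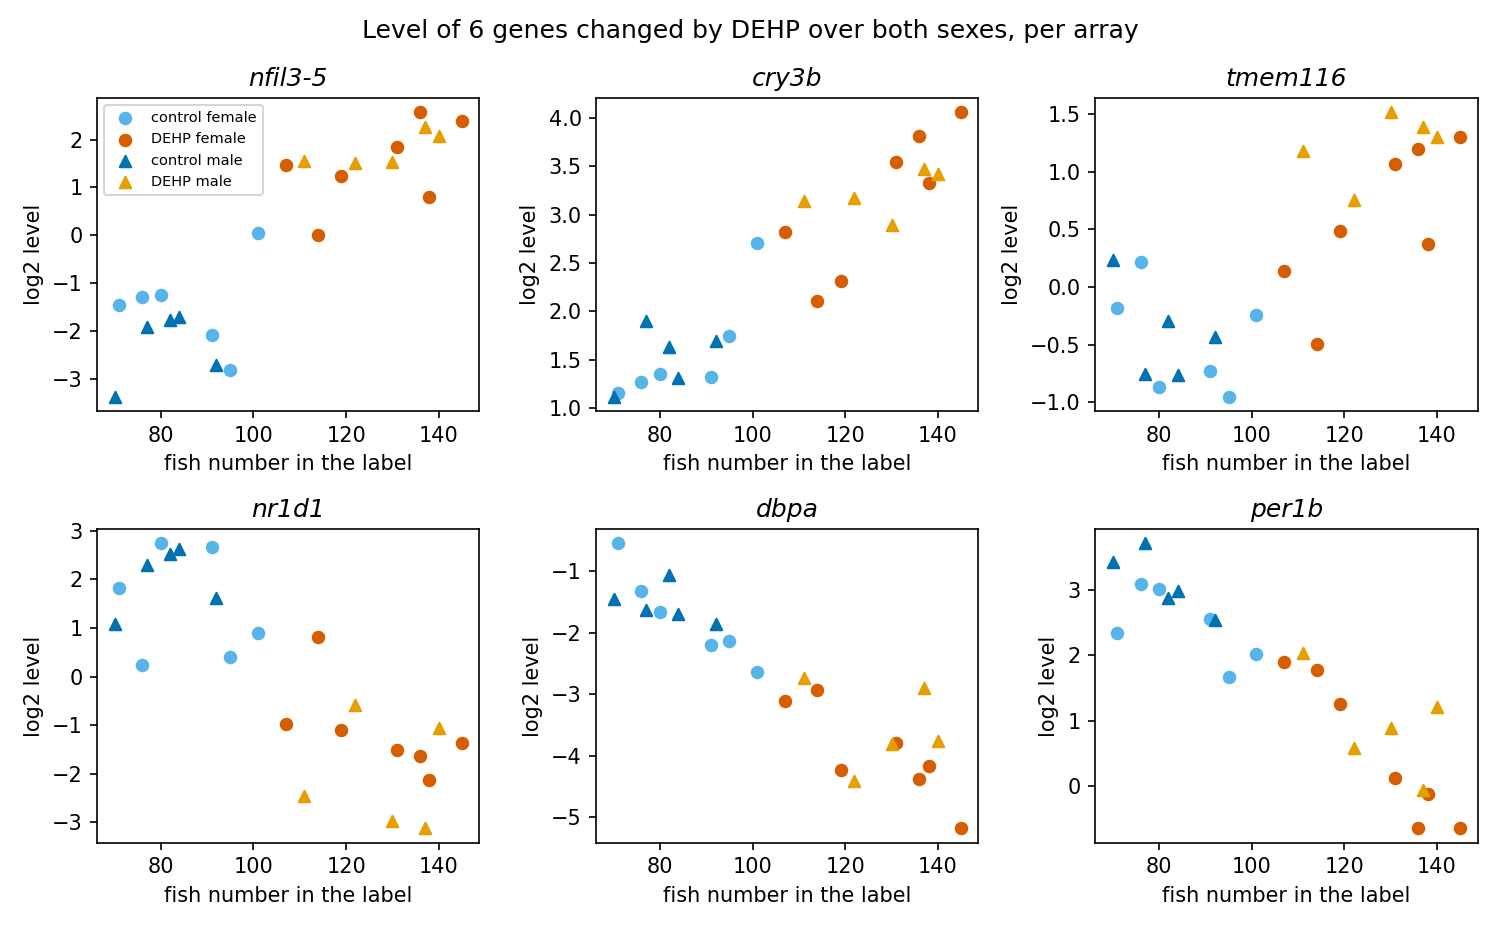
Level of 6 genes (log2 signal relative to the 75th percentile of the array) against the fish number in the label, with a point per array and colours and markers for the 4 groups. For nfil3-5 the highest control is 0.05 and the lowest exposed value 0.00, and 11 of 12 exposed arrays lie above every control array of their sex. The fish numbers of exposed fish and controls do not overlap.

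Over both sexes 10 of the 30 measured circadian clock members passed. Of these 2 rose (nfil3-5 and nfil3, the latter 1.18, adjusted p 0.0411) and 8 fell, including tefa (-1.70, adjusted p 0.000752) and cipcb (-1.42, adjusted p 0.0247); 7 rose and 13 fell adjusted over the list alone. Besides the genes named by rule, these and the next members were chosen after their values were seen. The activator genes bmal1a (1.05) and bmal1b (1.69), which cycle in antiphase to the period genes, did not pass. The list shifted down (mean -0.44, 12 of 12 arrays, adjusted p 6.82e-05; adjusted p = 0.0593 with an estimated correlation; fry adjusted p 0.00145). That call was lost with the fish number as covariate (adjusted p 0.320, mean -0.13). With slide as a fixed block 25 probes passed, nfil3-5 (3.67, adjusted p 0.000517), nr1d1 (-3.32, adjusted p 0.0107), ciarta (-2.25, adjusted p 0.0205), cry2 (-1.60, adjusted p 0.0204), dbpa (-2.13, adjusted p 0.0191), cry5, cry3b and tmem116 (each adjusted p 0.0357) among them. No longer past the threshold were per1b (-1.87, adjusted p 0.0915), aif1l (adjusted p 0.12), ypel3 (adjusted p 0.156), gdf6a (adjusted p 0.29) and mylipb (adjusted p 0.334). With the fish number as a covariate limma called 0 probes, with 781 at an unadjusted p under 0.05: nfil3-5 was 2.42 (SE 0.70, adjusted p 0.999), nr1d1 -2.39 (SE 0.88), cry2 -1.06 (SE 0.44), and per1b turned to 0.35 (SE 0.48).

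The endocrine pancreas list shifted down over both sexes (mean -0.72, 18 genes, 12 of 12 exposed arrays below the control mean of their sex, adjusted p 6.54e-07; adjusted p = 0.0593 with an estimated correlation; fry adjusted p 0.00466). None of its members passed over all genes and 8 were lower adjusted over the list alone. Insulin (ins) stood at 6.95 ± 0.95 in control and 5.64 ± 0.90 in exposed females (SD, n = 6 and 7), and at 7.34 ± 0.89 in control and 5.56 ± 1.44 in exposed males (SD, n = 5 each). The log2 fold change over both sexes was -1.55 and did not pass (adjusted p 0.152, 10 of 12 arrays). Other values were -0.64 for pax6b, -0.88 for the islet factor gene isl1a, -1.07 for pcsk2, which turned to 0.84 with the fish number as covariate, and -1.23 for sst1.1. The list mean was lower on 3 of 3 slides in females and 4 of 4 in males, and its call held with slide as a block (adjusted p 3.2e-06) and with the fish number as covariate (adjusted p 0.011).

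Among the 14 lists called over both sexes, downward shifts were found for erythrocytes (mean -0.44, adjusted p 0.00309; adjusted p = 0.197 with an estimated correlation), enteroendocrine cells (-0.32, adjusted p 0.0106) and liver (-0.50, adjusted p 0.0165). Also lower were heat shock response (-0.28, adjusted p 0.0292; adjusted p = 0.114 with an estimated correlation; fry adjusted p 0.00466), extracellular matrix (-0.23, adjusted p 0.0367), fatty acid synthesis (-0.34, adjusted p 0.041) and xenobiotic metabolism and transport (-0.21, adjusted p 0.0411). A single member, named after its value was seen, fell in each of 3 of them: the heat shock factor gene hsf2 (-1.23, adjusted p 0.0109), the lysyl oxidase gene loxl2a (-1.90, adjusted p 0.00369) and mid1ip1l, a regulator of lipogenesis (-1.28, adjusted p 0.0489). Cell proliferation (0.24, adjusted p 0.0106), ovary and oocytes (0.51, adjusted p 0.0106), myeloid cells (0.21, adjusted p 0.0273), ribosomal proteins (0.09, adjusted p 0.0292) and lysosome-rich enterocytes (0.11, adjusted p 0.0367) shifted up. With an estimated correlation the adjusted p of these 12 lists was between 0.114 and 0.841, so 0 lists of the 39 were called. Myeloid cells, lysosome-rich enterocytes and ribosomal proteins were lost with quantile normalization (adjusted p 0.224, 0.428 and 0.771, the ribosomal proteins turning down), and fatty acid synthesis and lysosome-rich enterocytes with slide as a block (adjusted p 0.103 and 0.113). The fish number as covariate ended the calls of liver (adjusted p 0.0909, mean turning to 0.78), heat shock response (0.629, turning to 0.01), matrix (0.186), xenobiotic metabolism (0.190), myeloid cells (0.289), ovary (0.296) and lysosome-rich enterocytes (0.763). Named members that did not pass included slc4a1a (-1.18), sptb (-0.92, turning to 0.04 with normexp background correction), hbba2 (-1.21), rhag (-0.91; 0.04 with the fish number as covariate), hmgb2a (-0.99), mcm5 (-0.63), kif4 (0.81), aurkb (0.85), h1-10 (0.64), wee2 (0.79; -0.08 with that covariate), cth1 (1.07) and rbpms2b (0.47). The targets did not pass either: pparaa 0.07 (adjusted p 0.914), cyp1a -0.93 (adjusted p 0.353), cyp3a65 0.06 (adjusted p 0.956), nr1i2 -0.32 (adjusted p 0.736) and vtg1 -0.92 (adjusted p 0.8). The values of pparaa and cyp3a65 changed sign with normexp background correction (-0.05 and -0.04) and nr1i2 with quantile normalization (0.12).

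Whether the sexes differed in their response was tested as the female minus the male effect. No probe passed limma's test (902 at an unadjusted p under 0.05, smallest adjusted p 0.270), so no gene was shown to respond in 1 sex only. The 5 probes called in each sex separately had the same sign in both, where 0.00451 were expected for independent calls. The calls were not independent, since both tests used the same variance per probe and probes of 1 gene were counted apart. Across the 30180 probes the female and male effects correlated at r 0.0900 (rho 0.201); probes are not independent replicates, and 29 of 100 regroupings of treatment gave an r as large. The smallest adjusted p was that of the dimmer of 2 probes of mal (4.92, against 4.48 with an adjusted p of 1 at the other), named after its value was seen. By the brightest probe of each gene, the smallest p values belonged to mhc1uba, an antigen-presenting class I gene (7.84, SE 2.16), pde6a (-1.71 in females and 0.29 in males), cep72 (-2.12), bdkrb1 (-1.92), camk2n1a (-1.74), cnfn (3.41), fam120c (-2.29), adma (-1.55), s1pr4 (-2.19) and snx10b (-1.75), all with an adjusted p of 1.

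At the level of lists, 11 differed between the sexes in response by camera and 0 with an estimated correlation. The exocrine pancreas list gave a difference of 0.79 (adjusted p 6.66e-15; adjusted p = 0.308 with an estimated correlation), with ctrb.3 at 1.16, cela1.5 at 1.37, pla2g1b at 1.69 and cela1.1 at 1.04. Ovary and oocytes gave 1.94 (adjusted p 1.83e-12), with pou5f3 at 3.63 and the egg coat genes zp2.3 at 5.63 and zp2.5 at 4.88. Liver gave 1.11 (adjusted p 5.77e-08), with the coagulation factor gene f7 at 1.44. Both had adjusted p = 0.706 with an estimated correlation. The others were lysosome-rich enterocytes (0.40, adjusted p 3.69e-05, with ctsla at 1.14), skeletal muscle (-1.07, adjusted p 0.000307, with ttn.1 at -3.08) and vitellogenins (1.11, adjusted p 0.0136). Smaller differences were those of complement and acute phase (0.77, adjusted p 0.0241), tight junction (0.27, adjusted p 0.0287), T and NK cells (-0.40, adjusted p 0.0368), oxidative phosphorylation (0.11, adjusted p 0.0368) and lipid absorption (0.22, adjusted p 0.0368). With an estimated correlation these had adjusted p = 0.706 or 0.783. With quantile normalization lipid absorption (adjusted p 0.853), oxidative phosphorylation (0.839, turning down), T and NK cells (0.175), complement (0.475), tight junction (0.0989) and vitellogenins (0.0989) were lost. Complement was also lost with slide as a block (0.0680) and, like T and NK cells, with the fish number as covariate (0.0935 and 0.0683). The clock list did not differ (-0.06, adjusted p 0.83).

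**Figure D2:**
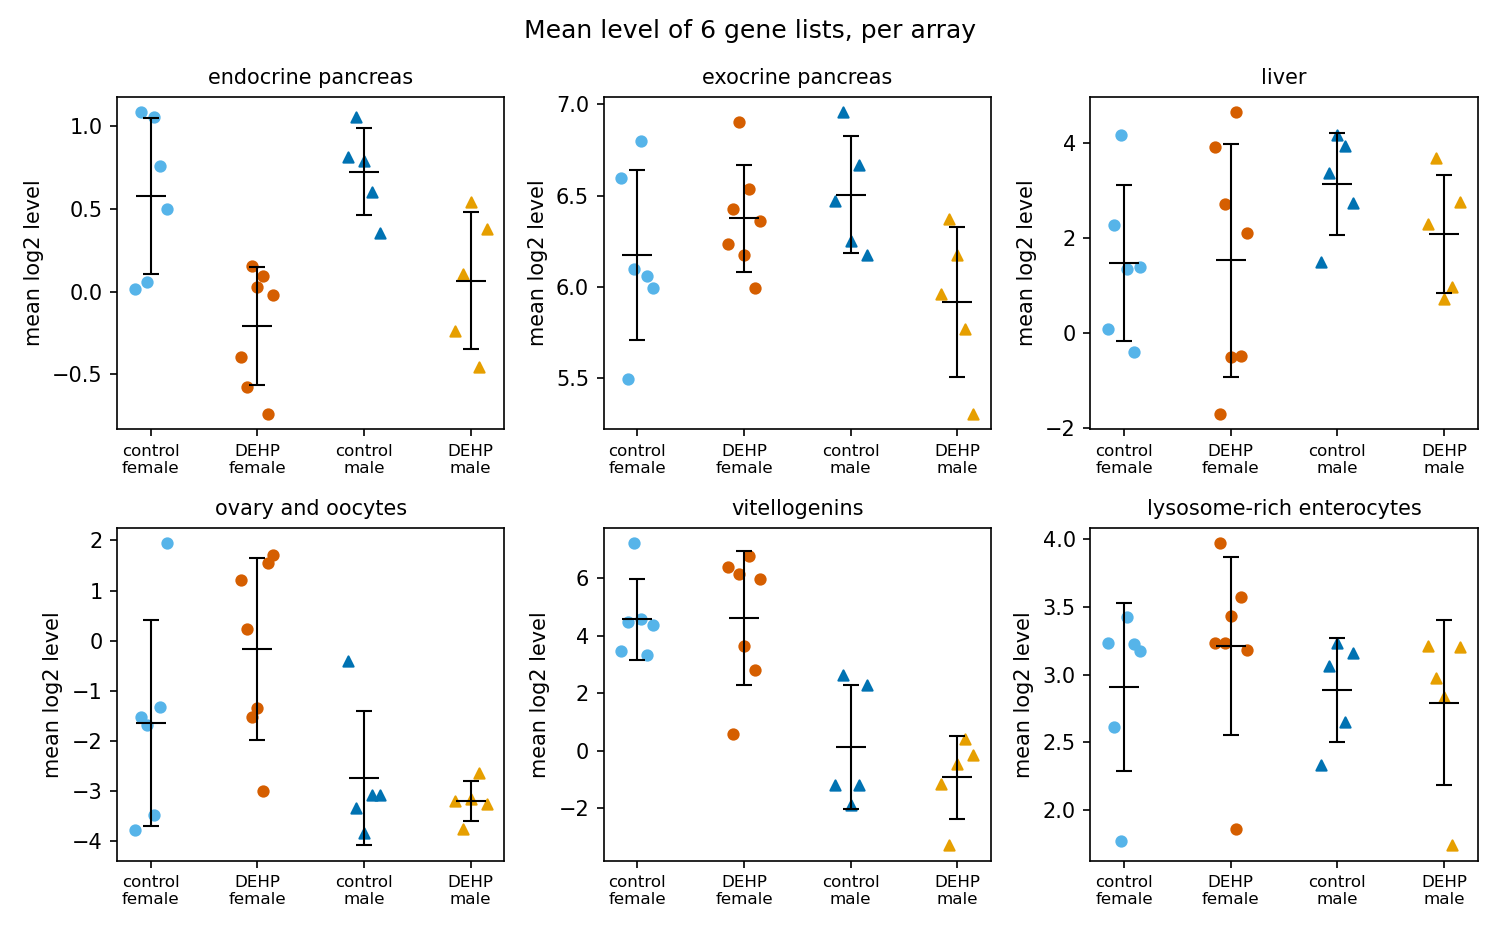
Mean level of 6 gene lists per array (log2 signal relative to the 75th percentile of the array), with a point per array in each of the 4 groups and the mean ± SD. The endocrine pancreas list averages 0.58 and 0.72 in control females and males and -0.21 and 0.06 in exposed ones, while the ovary list spreads from -3.78 to 1.95 over the 6 control females.

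The design also allows females and males to be compared within each treatment. Among controls 12 probes passed, 2 higher and 10 lower in females, from 8 genes. The cytochrome P450 gene cyp2k6 was 68.5-fold higher in females (log2 6.10, SE 0.67, adjusted p 4.61e-05; chromosome 3, 12443101 to 12443160), at 2.95 ± 0.67 against -3.15 ± 0.85 (SD, n = 6 and 5). The gene eevs, for an enzyme of gadusol synthesis, was 29.6-fold higher (SE 0.60, adjusted p 0.000217). In males thrsp, a regulator of lipogenesis, was higher (log2 -6.66, SE 1.02, adjusted p 0.00432), and trim35-9, of the TRIM family, at least 19.3-fold higher (SE 0.61, adjusted p 4.61e-05; chromosome 3, 8841059 to 8841118). So were the mitochondrial carrier gene slc25a48 (35.7-fold, SE 0.70, adjusted p 0.00106) and hsd17b3, a hydroxysteroid dehydrogenase of androgen synthesis (log2 -3.59, SE 0.50, adjusted p 0.00138). The taurine synthesis gene csad (5.41-fold higher in males, adjusted p 0.0341) and the sulfate transporter gene slc26a2 (2.74-fold, adjusted p 0.0389) also passed. For all 8 genes 6 of 6 females lay beyond every male. On the 2 slides with both sexes cyp2k6 was higher in females (6.38 and 7.54) and trim35-9 lower (-7.50 and -3.01). With slide as a fixed block cyp2k6 (6.41, adjusted p 0.00674) and trim35-9 (-5.31, adjusted p 0.00768) passed and eevs (adjusted p 0.0588), thrsp (adjusted p 0.61), slc25a48 and hsd17b3 (each 0.257), csad and slc26a2 (each 0.79) did not. Of these genes csad and slc26a2 were also lost with the fish number as covariate (adjusted p 0.0603 and 0.0722) and without control females 71 and 76 (0.121 and 0.0539), and each passed in 12 of 23 fits that left out 1 array.

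Yolk protein transcripts separated the control sexes as a group. The vitellogenin list, 12 genes, was higher in control females (mean log2 difference 4.45, 6 of 6 females above every male, adjusted p 1.65e-15; adjusted p = 0.157 with an estimated correlation; exact permutation p 0.00216). None passed over all genes and 10 were higher adjusted over the list alone, with vtg5 at 6.08 (adjusted p 0.123), vtg4 at 6.42, vtg6 at 5.33 and vtg7 at 4.84. The level of vtg1 spread from 0.01 to 7.59 over the 5 control males and from 7.42 to 11.37 over control females. Liver (-1.67, adjusted p 9.13e-11; adjusted p = 0.427 with an estimated correlation) and complement (-1.49, adjusted p 1.58e-06) were higher in control males, with hpxa at -5.02, hamp at -3.03, ahsg2 at -3.79, c8a at -3.20 and c4 at -1.43, none past the threshold. Lists of enterocyte metabolism were higher in males too: oxidative phosphorylation (-0.35, adjusted p 5.85e-09), lipid absorption (-0.56, adjusted p 5.82e-08; exact permutation p 0.00433), fatty acid oxidation (-0.34, adjusted p 6.8e-06), brush border (-0.31, adjusted p 0.000354) and oxidative stress response (-0.31, adjusted p 0.00209). Their members uqcrh (-0.70) and atp5f1b (-0.72) of the respiratory chain, creb3l3a (-1.20), slc27a2a (-1.30), fabp2 (-0.82), apoa2 (-2.75) and acaa2 (-0.86) did not pass. Also higher in males were interferon response (-0.46, adjusted p 3.05e-05), exocrine pancreas (-0.33, adjusted p 0.00256), ribosomal proteins (-0.17, adjusted p 0.0133), nuclear receptors (-0.20, adjusted p 0.0316) and antigen processing (-0.52, adjusted p 0.0414). Higher in females were ovary and oocytes (adjusted p 6.63e-05), cholesterol synthesis (0.86, adjusted p 7.29e-05), testis and sperm (0.49, adjusted p 0.0034), cell proliferation (0.31, adjusted p 0.0336) and skeletal muscle (0.47, adjusted p 0.0414). With an estimated correlation 0 of these 18 lists were called (adjusted p = 0.157 to 0.802). On the 2 slides with both sexes the ovary list was lower in females (-3.06 and -0.58). After blocking on slide, fatty acid oxidation (adjusted p 0.0757), oxidative stress, nuclear receptors, brush border and skeletal muscle (each 0.133, the last turning to -0.39), exocrine pancreas (0.232), ovary (0.4) and proliferation (0.0978) were lost. With normexp background correction the losses were oxidative phosphorylation (0.152), antigen processing (0.997), testis and sperm (0.375, mean -0.02) and ribosomal proteins (0.265, turning up). With quantile normalization fatty acid oxidation, oxidative stress, nuclear receptors, antigen processing, brush border, exocrine pancreas, proliferation and ribosomal proteins were lost (adjusted p 0.0579 to 0.778). The ribosomal proteins were lost with the fish number as covariate too (0.0538).

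Among exposed fish 118 probes passed, 97 higher and 21 lower in females. Vitellogenin genes led: vtg2 was 308-fold higher in females (log2 8.27, SE 1.59, adjusted p 0.019), vtg4 199-fold (adjusted p 0.0141), vtg5 152-fold (adjusted p 0.0102) and vtg1 99.0-fold (SE 1.42, adjusted p 0.0411). Of the 12 vitellogenin list members 8 passed, all higher, and 11 were higher adjusted over the list alone (mean 5.56, 7 of 7 females above every male, adjusted p 1.94e-24). That call held with an estimated correlation (adjusted p = 0.0248 with an estimated correlation), by fry (adjusted p 0.00162) and with slide as a block (3.67e-13). Higher too were nots, a protease gene of the female liver (141-fold, adjusted p 0.0291), cyp2k6 (125-fold, SE 0.64, adjusted p 5.05e-06) and the coagulation factor gene f13a1a.1 (at least 2.59-fold, adjusted p 0.0109). Higher in males were trim35-9 (at least 20.9-fold, SE 0.59, adjusted p 5.05e-06), thrsp (27.9-fold, adjusted p 0.0303), slc25a48 (20.3-fold, adjusted p 0.00498), hsd17b3 (5.58-fold, adjusted p 0.0211), faah, which breaks down fatty acid amides (5.25-fold, adjusted p 0.00878), and msantd4 (3.87-fold, adjusted p 0.0411). For each of these named genes 7 of 7 females lay on the same side of the male mean. Of the 12 probes called among controls 9 were called here with the same sign, where 0.0469 were expected for independent calls. These calls also shared a variance per probe, and probes of 1 gene were counted apart. On the 3 slides with both sexes cyp2k6 (4.01 to 8.92) and vtg2 (4.81 to 9.70) were higher in females on each. With slide as a fixed block 19 probes passed, cyp2k6 (7.07), trim35-9 (-6.22) and f13a1a.1 (3.61) among them, whereas vtg2 (7.78, adjusted p 0.151), vtg4 (0.146), vtg5 (0.137), vtg1 (6.35, adjusted p 0.185) and nots (0.155) did not. Nor did thrsp (adjusted p 0.191), slc25a48 (0.0862), hsd17b3 (0.150), faah (0.0523) and msantd4 (0.0699). With the liver, ovary and pancreas levels as covariates 6 probes passed, and of the named genes only cyp2k6 (adjusted p 0.0136) and trim35-9 (0.0406); vtg2 went to 9.05 (SE 2.29, adjusted p 0.244), so its error grew while its value did not fall. Leaving out 1 array gave 33 (without exposed male DM111) to 354 probes (without exposed female DF136). The value of vtg2 then lay between 6.99 (without exposed male DM122) and 9.24 (without exposed female DF114), and for the same fish that of vtg1 between 5.23 and 7.30, of vtg4 between 7.01 and 8.57 and of vtg5 between 6.59 and 8.07. That of nots ranged from 6.52 (without DF136) to 8.12 (without DF114), that of thrsp from -5.57 (without DM137) to -4.16 (without DM122), and that of cyp2k6 rose to 7.82 without DM137. Over these 23 fits vtg2 passed in 19, vtg4 in 21, vtg1 in 14, nots in 16, thrsp in 15, hsd17b3 in 20, msantd4 in 11 and the others named in 23.

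**Figure D3:**
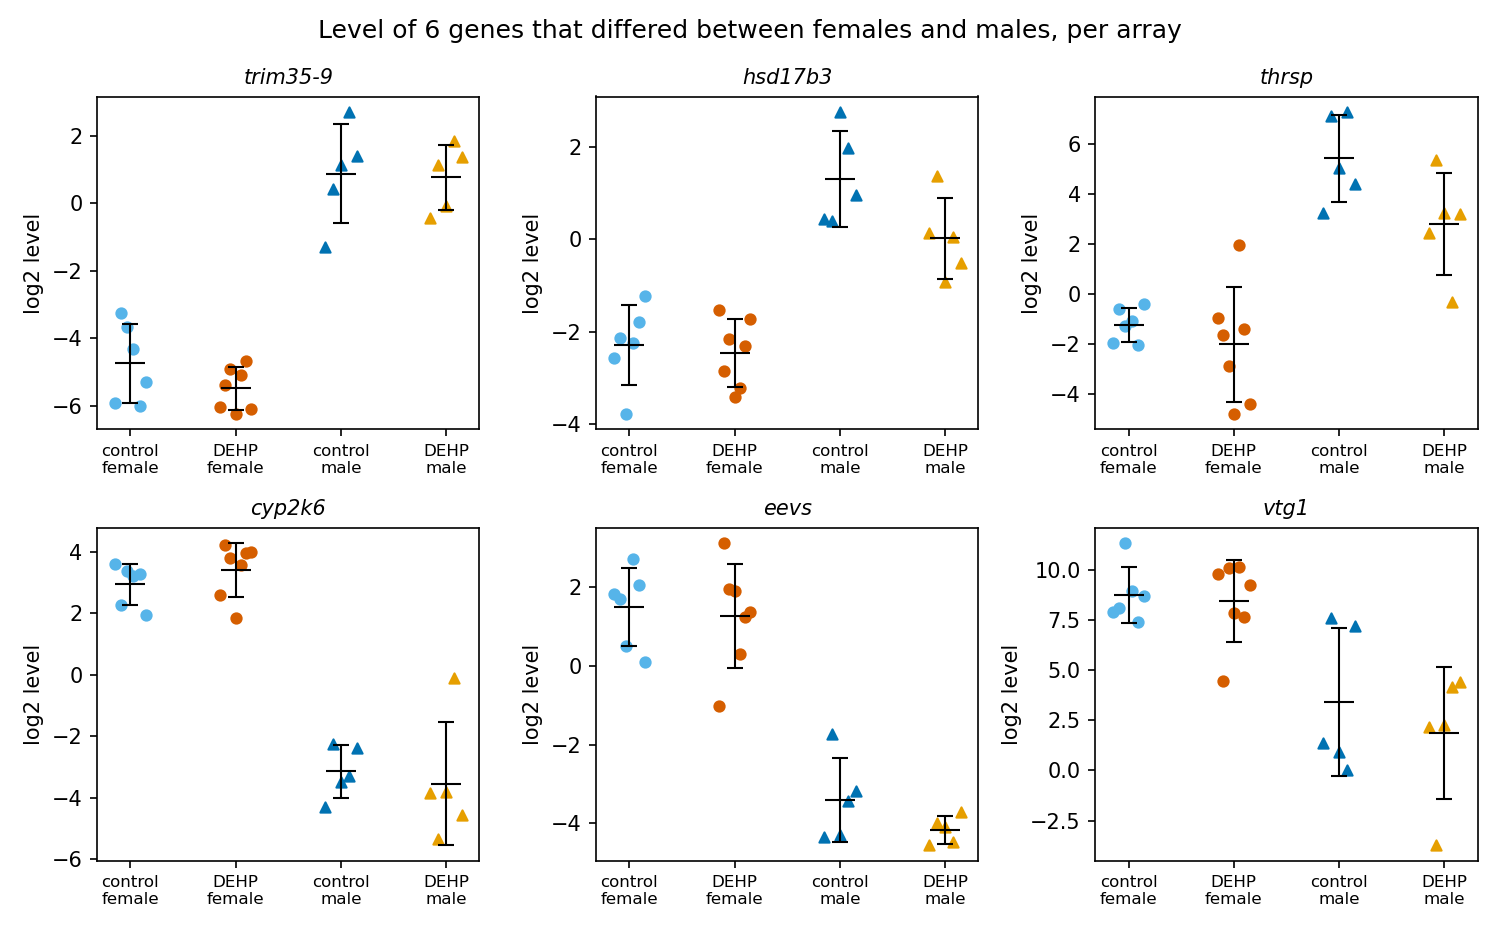
Level of 6 genes (log2 signal relative to the 75th percentile of the array) in the 4 groups, with a point per array and the mean ± SD. cyp2k6 and eevs are higher and trim35-9, hsd17b3 and thrsp lower in females of both treatments, and vtg1 spreads from 0.01 to 7.59 over the 5 control males.

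Ovary and oocyte transcripts were higher in exposed females than in exposed males (mean 3.04, 45 genes, 7 of 7 females above the male mean, higher on 3 of 3 slides, adjusted p 4.22e-27; adjusted p = 0.367 with an estimated correlation; exact permutation p 0.00631). Of its members 0 passed over all genes and 30 adjusted over the list alone. The egg coat gene zp2.5 was at least 23.8-fold higher (adjusted p 0.0806), zp3a.1 at least 37.7-fold and zpax1 at least 17.2-fold (each adjusted p 0.0843), none past the threshold. Exocrine pancreas (0.46, adjusted p 4.38e-06), cell proliferation (0.56, adjusted p 1.54e-05), lysosome-rich enterocytes (0.42, adjusted p 0.000125) and cholesterol synthesis (0.40, adjusted p 0.0251) were higher in females. Members were pdia2 at 1.38, the cyclin genes ccnb1 at 2.73 and ccnb2 at 2.32, and gla at 1.53, none past the threshold. With the liver, ovary and pancreas covariates the proliferation list turned to -0.56 (adjusted p 0.000559), with ccnb1 at -0.74 and ccnb2 at -1.04. Interferon response (-0.65, adjusted p 1.8e-05), brush border (-0.31, adjusted p 0.00174; exact permutation p 0.00126, adjusted 0.0492), oxidative phosphorylation (-0.24, adjusted p 0.00301), lipid absorption (-0.34, adjusted p 0.0106), fatty acid oxidation (-0.26, adjusted p 0.0216) and T and NK cells (-0.30, adjusted p 0.0251) were higher in males. The antiviral genes pkz, usp18 and ifih1 stood at -1.30, -0.99 and -0.61, none past the threshold. Apart from the vitellogenins no list was called with an estimated correlation (adjusted p = 0.367 to 0.809). With normexp background correction, which moved the median of all probes from -0.05 to -0.24 in this contrast, brush border, oxidative phosphorylation, lipid absorption and fatty acid oxidation turned up (means 0.01, 0.18, 0.04 and 0.06) and interferon response was lost (adjusted p 0.0663). Blocking on slide lost the 4 metabolic lists (adjusted p 0.25, 0.469, 0.25 and 0.719).

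Gene lists without a call in any of the 6 contrasts were glycolysis and gluconeogenesis (34 genes, mean -0.10 over both sexes, adjusted p 0.724), bile acid handling (10 genes, 0.03, adjusted p 0.471) and B cells and immunoglobulins (10 genes, -0.05, adjusted p 0.985). Likewise uncalled were goblet cells and mucus (16 genes, -0.15, adjusted p 0.679), smooth muscle (29 genes, -0.17, adjusted p 0.132), enteric neurons and glia (36 genes, -0.19, adjusted p 0.107) and iron and hypoxia response (33 genes, -0.01, adjusted p 0.94). Among lists called only between the sexes, the exposure effect over both sexes was 0.05 for fatty acid oxidation and PPAR alpha targets (adjusted p 0.15), 0.03 for oxidative stress response (adjusted p 0.531) and 0.03 for antigen processing (adjusted p 0.107). It was 0.01 for interferon response (adjusted p 0.545), -0.07 for brush border (adjusted p 0.724) and -0.11 for testis and sperm (adjusted p 0.819). Median, mean and test of a list differed in sign in some uncalled lists, as for glycolysis in males (median 0.08, mean -0.08), antigen processing in males (0.17 and -0.26), goblet cells in females (0.09 and -0.14) and vitellogenins in females (-0.11 and 0.05). The number of arrays limits the precision of all these values.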

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

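Chosen only after the result was seen were the tests of the clock arms, of ovarian tissue and of female RNA in control males, the fits with array brightness, the fish number or tissue levels as covariates, and the fits without control females 71 and 76. Below, C is control, D is DEHP, F is female and M is male in the names of fish.

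The clock genes that differed between exposed and control fish are the pattern most in need of a further experiment. Array brightness and carry-over of liver, ovary and pancreas are argued against as causes: the median absolute log2 fold change of the 10 called clock genes (2.05) stood at 1.001 times its value with brightness as covariate (0.979 to 1.03 over fits leaving out each array) and at 0.963 times with the 3 tissue levels (0.923 to 1.02). Sampling in the order of the fish numbers stays open as a candidate explanation. The clock index is the mean of genes placed with the period genes (period arm) minus that of genes placed with bmal1a and bmal1b (bmal1 arm). Within groups it changed by -0.0330 per number (95% interval -0.0510 to -0.0150, permutation p 0.00152), and a slope of -0.0433 would give the whole difference. With the number in the model the difference in the index went from -1.89 (-2.39 to -1.40) to -0.451 (-1.30 to 0.398), and calls ended because estimates shrank and errors grew, numbers and treatment having no overlap. A different clock phase at sampling was left undecided by a difference of -1.53 between the arms, since only 2 genes of the bmal1 arm passed. An effect of DEHP stays open too, as with the number in the model nfil3-5 kept 2.42 (SE 0.70) of 3.52 (SE 0.32) and nr1d1 -2.39 (SE 0.88) of -3.33 (SE 0.39), neither past the threshold.

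Ovary transcripts were higher in exposed females by 1.48 in the list mean, but the list was not called with an estimated correlation (adjusted p = 0.803), its exact permutation p was 0.189, and its levels overlapped (-3.78 to 1.95 in controls, -3.01 to 1.71 in exposed females), so chance stays open. Brightness is argued against, as 1.01 times the difference was left with it as covariate (0.974 to 1.12). Ovarian tissue in some dissected guts is a candidate explanation, since the list members rose and fell together over the 13 female arrays corrected for treatment (median pairwise correlation 0.776, against at most 0.0697 for random gene sets). Whether such tissue also lies behind 2 other shifts was left undecided, because the test required both lists to agree and they did not. With the ovary level as covariate 0.160 of the cell proliferation shift was left, so most of that shift went with the ovary level. Of the lysosome-rich enterocyte shift 0.865 was left, so most of that shift did not. Whether dissection or an effect of DEHP lies behind a difference, if there is one, was not tested.

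The vitellogenin levels of control males CM77 and CM92 lay near those of females, which was seen in the data. From a female at the mean level of control females, RNA would have to make up 45.0% and 35.0% of those arrays to give their vtg1 level. At that level cyp2k6 allows at most 2.74% and 2.47%, and eevs 10.8% and 3.91%, which argues against such RNA as the whole cause. The share needed is smaller for a female with more vtg1, whose level ranged from 7.42 to 11.37 over control females. Contact of these males with an estrogen was not tested and stays open.

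Other groupings of the samples, 100 per comparison with the real one, tell how often chance alone gave as many probes. The real count was the highest over both sexes (95 probes, reached by 1 of 100, highest other 1), which argues against chance. It was also the highest for control females against control males, but narrowly (12 probes, 1 of 100, highest other 11). Other groupings gave more probes than the real one for females (17 probes, 2 of 100, highest other 359), for males (8 probes, 4 of 100, highest other 2412) and for exposed females against exposed males (118 probes, 2 of 100, highest other 282). Such counts were rare, but chance is not excluded there. The groupings ignored the slides, and no correction was made for the number of comparisons. For the difference between the sexes in response the count was 0 by limma (902 at an unadjusted p under 0.05), which any grouping reaches (100 of 100, highest other 163), so the groupings say nothing on chance there. The groupings with 359 and 2412 probes mixed the treatments and point to a structure of the samples other than treatment. The grouping with 551 probes stayed close to the treatments, as only 1 pair of fish changed places. The grouping with 282 probes held exposed fish only and stayed close to the sexes, with DF131 and DF136 placed among the males. The grouping with 359 probes set CF91, CF101, DF114, DF131, DF138 and DF145 against the other females, with 3 of 6 and 5 of 7 in scan 1. Of the gene lists, complement and acute phase stood furthest apart there. Liver list means were -1.72 to 0.08 in the 6 fish apart from DF145 (2.09), and 1.34 to 4.66 in the other females. What lies behind this was not tested. Among males 551 probes were called when CM70 and DM122 changed places (1 of 5 and 3 of 5 in scan 1), and 2412 with CM70, CM77, DM111, DM130 and DM137 on one side (3 of 5 and 1 of 5). The lists furthest apart were extracellular matrix in the former and testis and sperm in the latter. The grouping with 282 probes set DM111, DM122, DM130, DF131, DF136, DM137 and DM140 against the other exposed fish, with 3 of 7 and 3 of 5 in scan 1. Ovary and oocytes was the list furthest apart in it. With scan as a block the real groups gave 18 probes in females, 8 in males and 86 between exposed sexes. With slide as a fixed block they gave 0, 2 and 19.

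Single samples stood far from the rest of their group in 49 of 732 sets of values tested, where chance gives about 1 in 20 (36.6), so single cases carry little weight. Values are log2 levels except where said. CM70 had 13 of them. Its genes were cnfn (-4.49), ctsd (5.36), f7 (-2.78), hamp (0.13), ifih1 (1.84), pkz (4.98), rbpms2b (0.72), slc27a2a (4.84), ypel3 (1.31) and zpax1 (0.39), and its lists were interferon response (2.76), ovary and oocytes (-0.41) and iron and hypoxia response (1.31). CF76, the dimmest array, had 10, with hmgb2a (3.12), mcm5 (0.97), msantd4 (0.98), nots (8.44), nr1i2 (-3.62), sst1.2 (-0.27), vtg6 (11.70), vtg7 (12.37), tight junction (0.50) and vitellogenins (7.23). DF136 stood apart in agxta (3.41), ifi27.4 (2.93), sptb (-5.02), zp2.3 (-4.72) and lysosome-rich enterocytes (1.86). DM137 did in birc5a (-4.27), sst1.1 (0.20), zp3.2 (-3.31) and lysosome-rich enterocytes (1.74), and DM122 in vtg1 (-3.74), vtg2 (-5.82), vtg7 (0.076) and iron and hypoxia response (2.01). CM77 differed in cela1.1 (8.39), bile acid handling (3.66) and erythrocytes (-0.63), CF95 in acp5a (3.42) and kif4 (0.22), and DF119 in cnfn (-5.01) and ctsd (5.99). CF71 differed in lgmn (3.32) and in its 413 non-uniform features, with 11 on the next array. Others were c4 in CM92 (-0.31), c6ast4 in DF107 (4.33), nr1d1 in DF114 (0.80) and sst1.1 in DF138 (1.56).

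The mean shifts of 11 lists differed between the sexes in the test of the female minus the male DEHP effect. The differences were 0.22 for lipid absorption, 0.11 for oxidative phosphorylation, -0.40 for T and NK cells, 0.77 for complement, 0.40 for lysosome-rich enterocytes, 0.27 for tight junction, 0.79 for exocrine pancreas, 1.11 for liver, 1.11 for vitellogenins, 1.94 for ovary and -1.07 for skeletal muscle. With an estimated correlation 0 lists were called there (smallest adjusted p 0.308).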

How the results depend on the processing

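In fish names C is control, D is DEHP, F is female and M is male. Chosen after the data were seen were the fits without CF71 and CF76 and those with array brightness, the fish number, or liver, ovary and pancreas levels as covariates. Signal over background limits all counts, since 12966 of 30180 tested probes were well above background on all arrays. Over the settings other than leaving out an array, 511 of 576 values of named genes in females kept their direction and side of the threshold, 546 of 569 in males, 492 of 545 over both sexes, 461 of 461 in the difference between the sexes, 464 of 499 between control sexes and 440 of 493 between exposed sexes. Most of these genes were not past the threshold, so keeping the side says little on the calls. In females nfil3-5 passed in 12 of 16 of these settings, cry5 in 11, dbpa in 10, angptl1a in 7 and ankrd9 in 5. Also in females, cry2 passed in 11 of 17 and tefa in 9 of 17. In males nfil3-5 passed in 14 of 16, nr1d1 in 10 of 16 and ciarta in 11 of 17. Over both sexes nfil3-5 passed in 14 of 15, mylipb in 8 and gdf6a in 5. Counts that stayed within 1.5 times the values of the report under a setting are not listed. Lists were not tested with slide as a random block, which camera does not take. A fit of only the 2 groups has no value for contrasts over 4 groups. Except where fewer probes or arrays enter by construction, the cause was not tested. With normexp background correction 2 probes passed in females, 0 in males, 25 over both sexes and 75 between exposed sexes. Called were 22 lists over both sexes, 22 in the difference between the sexes and 23 between exposed sexes. There ogna turned to 0.21 and pparaa to -0.10 in males, and sptb to 0.036, pparaa to -0.052 and cyp3a65 to -0.044 over both sexes. Quantile normalization gave 11 probes in females, 5 in males, 63 over both sexes and 20 between control sexes. It gave 5 lists in the difference between the sexes and 11 between control sexes. There nr1i2 turned to 0.53 in females and 0.12 over both sexes, and cyp3a65 to -0.054. The deposited table gave 5 probes in males and 35 between control sexes (13 higher and 22 lower in females, against 2 and 10), 5 lists in the difference between the sexes and 11 between control sexes. There nr1i2 turned to 0.45 in females and 0.080 over both sexes, and cyp3a65 to -0.054. Median scaling turned pparaa to 0.074 in females. Without a filter 5 probes passed in males, 59 over both sexes and 76 between exposed sexes. With probes well above background on all arrays, which tests fewer probes, 5 passed in females, 1 in males, 0 between control sexes by limma (992 unadjusted) and 53 between exposed sexes. On those probes 6 lists were called in the difference between the sexes and 7 between exposed sexes, and the effects of the sexes correlated at 0.294 across probes. With slide as a fixed block 0 probes passed in females, 2 in males, 25 over both sexes, 4 between control sexes and 19 between exposed sexes, with 11 lists between control sexes. The fit of only the 2 groups gave 2 probes in females, 1 in males and 232 between exposed sexes. Array weights gave 61 probes in females, 13 in males, 213 over both sexes, 121 between control sexes and 417 between exposed sexes. They gave 20 lists in females, 7 in the difference between the sexes and 9 between control sexes. There pparaa turned to -0.058 over both sexes. The exocrine pancreas covariate gave 1 probe in males and 311 between exposed sexes. It gave 11 lists in males and 9 over both sexes. There cyp3a65 turned to -0.012 over both sexes. At an adjusted p of 0.1, 42 probes passed in females, 13 in males, 147 over both sexes and 292 between exposed sexes. At an unadjusted p of 0.05 with 1.5-fold change the counts were 2903 in females, 1070 in males, 1980 over both sexes, 902 in the difference between the sexes, 2582 between control sexes and 2978 between exposed sexes. Means over the probes of a gene gave 62 over both sexes and 20 between exposed sexes. Camera with an estimated correlation called 0 lists in females, males, over both sexes, in the difference between the sexes and between control sexes, and 1 between exposed sexes. The fry test called 3 in females, 0 in males, 3 over both sexes, 0 in the difference, 1 between control sexes and 1 between exposed sexes. Without CF71 and CF76, which leaves fewer arrays, 0 probes passed in females (1167 unadjusted) and 59 over both sexes. On these arrays 16 lists were called in females, vtg1 turned to 0.24 in females and the effects of the sexes correlated at -0.0471 across probes. With the fish number 0 probes passed in females, males and over both sexes (543, 1181 and 781 unadjusted). With it 16 lists were called in females and 12 in males, and the effects of the sexes correlated at 0.589. That correlation can rise by construction, because both sexes shared 1 slope per probe for the number. With the fish number as covariate, pcsk2 in females turned to 0.10, ctsla to -0.42, pparaa to 0.17 and cyp3a65 to -0.12. In males pla2g1b turned to 0.047, ugt5a1 to 0.037 and gsta.2 to 0.22. Over both sexes it turned per1b to 0.35, pcsk2 to 0.84, rhag to 0.036, wee2 to -0.079 and cyp3a65 to -0.48. With the liver, ovary and pancreas covariates 3 probes passed in females, 2 in males, 62 over both sexes, 100 between control sexes and 6 between exposed sexes. With these covariates 5 lists were called in females, 11 in males, 9 over both sexes, 5 in the difference, 11 between control sexes and 7 between exposed sexes. There pparaa turned to 0.15 and vtg1 to 0.16 in females, cyp3a65 to -0.035 over both sexes, and birc5b to -0.34, ccnb1 to -0.74 and ccnb2 to -1.04 between exposed sexes. Leaving out each array in turn gave 2 to 24 probes in females (2 without CF71, 9 without CF91, 11 without DF131, DF138 or DF145, 2 without DF136). In males it gave 4 to 11 (5 without CM77 or CM82 and without DM137 or DM140, 4 without CM84 or CM92). Over both sexes it gave 54 to 105 (63 without CF71 or DF131 or DF145, 54 without DM140). The difference between the sexes gave 0 to 1 (1 without CM70). Control sexes gave 9 to 45 (42 without CM92, 45 without DF114), and exposed sexes 33 to 354 (352 without CF95, 49 without DF107 or DF119, 354 without DF136, 61 without DF145, 33 without DM111, 50 without DM122, 67 without DM130, 77 without DM137, 71 without DM140). Lists ranged from 9 to 21 in males (10 without CM92, 12 without DM111, 9 without DM130). They ranged from 7 to 18 over both sexes (8 without CF101, 9 without CM92 or DF131, 8 without DM130, 7 without DM137) and from 6 to 12 in the difference (7 without CM84, 6 without DF107). Values without an array ranged from -0.18 to 0.078 for pparaa and from -0.55 to 0.40 for vtg1 in females. They ranged from -0.00041 to 0.13 for pparaa and from -0.045 to 0.16 for cyp3a65 over both sexes, and from -0.0081 to 0.175 for the correlation of the sexes. Leaving out any array kept nfil3-5 past the threshold in females, in males and over both sexes (23 of 23 fits each), and nr1d1 in males. In females cry5, dbpa and cry2 passed in 21 (lost without CF71 or DF136), angptl1a in 17, tefa in 15 and ankrd9 in 13, and in males ciarta in 22 (lost without CM84). Over both sexes ypel3 passed in 15, mylipb in 13 and gdf6a in 4, and between control sexes csad and slc26a2 in 12. Between exposed sexes vtg4 passed in 21, hsd17b3 in 20, vtg2 in 19, nots in 16, thrsp in 15, vtg1 in 14 and msantd4 in 11. The other named calls passed in 23 of 23.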

Other observations

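The tests of the clock arms and of the clock index against the fish number were chosen after clock genes had been seen to lead the calls. The period arm of the clock was mostly lower in exposed fish and the bmal1 arm was mixed. Of 15 genes of the period arm, among them the period genes and nr1d1, 14 had a lower level in exposed fish over both sexes (6 past the threshold, median log2 fold change -0.81). Of 11 genes of the bmal1 arm, among them bmal1a, bmal1b and nfil3-5, 7 had a higher and 4 a lower level (2 past the threshold, median 0.72). The clock index, the mean of the period minus the bmal1 arm, was 2.46 ± 0.64 (SD, n = 6) in control females and 2.70 ± 0.56 (SD, n = 5) in control males, against 0.63 ± 0.70 (SD, n = 7) in exposed females and 0.73 ± 0.25 (SD, n = 5) in exposed males.

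Vitellogenin transcripts varied within groups as well as between the sexes. Over the 5 exposed males vtg1 ranged from -3.74 to 4.43 and over the 7 exposed females from 4.49 to 10.17. In females the vitellogenin list was lowest where the liver list was lowest (DF114, means 0.58 and -1.72). It was high where the liver list was high (6.78 and 4.66 in DF136, 7.23 and 4.16 in CF76). Males CM82 (-1.87 and 4.17) and DM122 (-3.29 and 3.69) had low vitellogenin with high liver levels. Whether the amount of liver tissue lies behind the spread in females was not tested. The estrogen receptor gene esr1, looked at after the vitellogenin values were seen, ranged from -1.57 to -0.67 over control males and from -0.68 to 4.03 over control females. The 4.03 was that of CF76, the dimmest array, and the next highest control female was CF71 at 0.15. The control males with high vitellogenin, CM77 (-1.01) and CM92 (-1.07), lay within the range of the other control males.

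A hypothesis drawn from these data is that the fish were sampled in the order of their numbers over the day. Within each treatment the clock index fell with the number: Pearson's r was -0.618 over the 11 controls (permutation p 0.0452, adjusted 0.0452; rho -0.664, permutation p 0.0308; -0.442 without the 2 fish farthest from the median number) and -0.713 over the 12 exposed fish (permutation p 0.00742, adjusted 0.0148; rho -0.727, permutation p 0.00967; -0.691 without 2), 2 relations in all, and index values were corrected for the mean of their group. The slope of -0.0330 per number fits the hypothesis in size, as far as that test goes. The test set no direction and the labels give no time of day, so the sign of the slope says nothing on it. Over all probes limma called 0 for the number within groups (2084 at an unadjusted p under 0.05), a count that any reassignment of the numbers reaches (100 of 100, highest other 427), so the reassignments say nothing on chance. Of the 95 probes changed over both sexes, 86 had a slope of the same sign as their DEHP effect. Of those 95, 39 had an unadjusted p under 0.05 for the slope. Slope and effect correlated at 0.422 over tested probes, which are not independent replicates. All 10 clock genes called over both sexes had the same sign. Of the clock genes 3 passed for the number adjusted over the list alone. Unadjusted p by limma was 1.47e-05 for per1b, 7.86e-05 for tefa and 0.000582 for dbpa. Slopes of other genes that led the DEHP calls were less certain (unadjusted p 0.0965 for nfil3-5, 0.177 for cry2, 0.249 for nr1d1 by limma).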
